A study of Mus musculus with 16 samples.

How the data were processed

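RNA abundance was measured on Affymetrix mouse expression arrays in lungs, heart and skin fibroblasts of NM1 knockout (KO) and wild-type (WT) mice. NM1, nuclear myosin 1, is an isoform made from the gene Myo1c and has been linked to transcription by RNA polymerase I and to chromatin remodelling. There were 16 arrays in 6 groups, with 3 KO and 3 WT mice for lungs, the same 6 mice for heart, and 2 KO and 2 WT fibroblast samples that carry other mouse numbers. Lungs and heart of 1 mouse were matched by the mouse number in the sample titles, KO 1602, 1603 and 1586 and WT 1592, 1624 and 1593. The fibroblast samples were KO 1584 and 1550 and WT 1571 and 1623. Each mouse number was read as a separate animal. The p-values rest on the spread between samples within a group. In the main model this spread is pooled over the 3 tissues, and lungs and heart of 1 mouse count as separate samples. Only in the comparison on the mean of lungs and heart is the mouse the unit. Per the labels, RNA was extracted with Trizol and 6 ug of total RNA was turned into biotin-labelled cRNA for each array.

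The deposited values are log2 signals, 1 per probe set and array, and Partek 6.4 is the tool named in the submitters' processing notes. The background correction, the summary of the probes and the normalization between arrays are not given in the sources used here. The log2 scale was read from the values themselves, whose array medians lay between 3.65 and 3.93. No total count or detection call goes with the values, so the number of arrays limits the precision. The smallest mean absolute difference between any 2 arrays was 0.190, so no array was a copy of another. The values were used as deposited, without a further normalization.

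Of 45141 entries, 104 control entries were set aside, leaving 45037 probe sets. The array annotation gives exactly 1 gene for 28898 of them, several genes for 551 and none for 15588, and the last are unnamed here, not without a gene. Of the probe sets with 1 gene, 28689 were matched to a current symbol by gene number, and 17097 distinct genes were covered. The probe sets of Myo1c do not tell its isoforms apart, and the part of the gene removed in the KO is not given in the sources used here. Gene order around Myo1c was taken from the RefSeq annotation of assembly GRCm38.p6, and no coordinates are given because the array names no assembly.

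Differences were tested with limma 3.58.1 in R 4.3.3. A single model with 6 group means was fitted to all 16 arrays, so that the groups shared 1 estimate of the spread per probe set (10 residual and 3.53 prior degrees of freedom). For each comparison, probe sets were kept when their mean over the arrays of a compared tissue lay above the median of all values, 3.79 on the log2 scale. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over the kept probe sets of that comparison, and an adjusted p under 0.05 was called. The comparisons were KO against WT in each tissue, the differences of these genotype effects between tissues, and WT lungs against WT heart. KO was also compared with WT on the mean of lungs and heart of each mouse, with 4 residual and 3.42 prior degrees of freedom. The mean of the 4 Myo1c probe sets was compared over the 3 tissues by a two-sided exact permutation test over mice, with lungs and heart of a mouse moved together and fibroblast samples moved apart from them. Within 1 tissue an exact test cannot go below p = 0.1 with 3 against 3 mice or 0.333 with 2 against 2. Effects of genotype were correlated across probe sets between tissues. Probe sets are not independent replicates, so these correlations carry no p-value.

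Pairing was checked from the data by correlating, for each of the 6 mice, the deviation of its lungs and of its heart from their group means. The correlation with the mouse's own heart was 0.0418, 0.0369, 0.163, 0.105, 0.178 and 0.0980 and was higher than with any other heart for 4 of 6 mice. Paired by mouse as a random block, the consensus correlation was 0.0542 over 16 arrays and 0.0261 over the 12 lungs and heart arrays.

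In all, 42 gene lists with 765 members were fixed, of which 672 were measured. They covered RNA polymerase I, ribosome biogenesis, NM1 partners, other myosins, functions of MYO1C outside the nucleus, p53 targets, cell cycle, mitochondria, glycolysis, matrix, muscle, bone, blood, clock, interferon, heat shock and immediate early genes, sex-linked genes, neighbours of Myo1c and markers of cell types. Each list was tested per tissue with camera of limma, with 1 probe set per gene (the one with the highest mean) and the preset correlation of 0.01, adjusted over the lists. The lists were also tested with an estimated correlation and with fry, and members were counted when adjusted over the list alone. Counts of members higher or lower cover only those kept by the filter in that tissue. The median and the list tests use all measured members.

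Genes were named by rule. These were all Myo1c probe sets, and per comparison up to 10 higher and 10 lower genes with the largest change among those called, filled up by the smallest p and then given as values that did not pass. To these were added up to 4 members per list and tissue, up to 10 genes called with 1 sign in several tissues, and up to 5 genes per difference between tissues. Of several probe sets of a gene, the one with the smallest p was used. Groups, comparisons, lists, the naming rule and most alternatives were chosen before the data were examined.

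The alternatives were no filter, a stricter filter at the 70th percentile (5.74 log2), quantile normalization, median centring, limma's trend and robust options, array weights, 1 probe set per gene, a threshold of 0.1 and unadjusted p under 0.05 with a 1.5-fold change. Mouse number as a random or fixed block, a fit per tissue and leaving out each array in turn were also run. Alternatives with terms for atrial or adipocyte transcripts, or without the arrays that stood apart in them, were chosen after seeing the data. The fit was tested on simulated data drawn with the spread of these arrays, in which changes of 2-fold were called for 56.1% of changed probe sets in lungs, 51.3% in heart and 39.7% in fibroblasts. Changes of 4-fold were called for 86.7%, 81.5% and 81.5%, and false calls made up 9.25%, 7.29% and 5.52% of all calls, above the nominal 5%. With the spread drawn instead from the prior of the fit, false calls made up 6.60%, 4.49% and 5.46%. Changes of 2-fold were then called for 59.7%, 63.0% and 36.7%. A simulated list shifted by 0.5 log2, that of oxidative phosphorylation, was called by camera in 5 of 5 simulations, with 0 other lists called. The simulated genes varied independently, while the estimated correlation of this list in the data was 0.719. The simulation therefore cannot show how often camera makes false list calls here. No sample was left out of the main values.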

Results

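Transcript levels were compared between NM1 KO and WT mice in lungs, heart and skin fibroblasts, on 16 arrays with 3 mice per genotype for lungs and for heart and 2 samples per genotype for fibroblasts. The question behind the series is what loss of NM1, an actin-based motor of the nucleus made from the gene Myo1c, does to gene expression in these tissues. Array medians lay between 3.65 and 3.93 log2. Arrays of 1 tissue correlated with r from 0.974 to 0.993 in lungs, 0.947 to 0.990 in heart and 0.986 to 0.993 in fibroblasts, across probe sets that are not independent replicates. The KO heart of mouse 1602 stood apart, with an upper quartile of 5.63 log2 against 6.17 to 6.31 in the other hearts, and without it the heart arrays correlated with r from 0.983 to 0.990. Every sample carried the markers of its labelled source. Sftpc, the surfactant protein of alveolar type II cells, lay between 13.9 and 14.1 log2 in lungs, Myl2, the ventricular myosin light chain, between 13.8 and 14.0 in heart, and the collagen gene Col1a1 between 10.9 and 11.6 in fibroblasts. Other markers were not confined to their source. The heart markers Actc1 and Tnnt2 lay between 7.46 and 11.6 and between 5.45 and 10.7 in lungs, and the lung marker Scgb1a1 reached 8.05 in heart.

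Myo1c transcript was lower in KO than in WT samples of all 3 tissues, and it remained detectable. The mean of its 4 probe sets fell by 1.35 log2 in lungs, from 8.0 ± 0.41 in WT to 6.65 ± 0.40 in KO (SD, n = 3), which is 2.55-fold lower. In heart it fell by 0.75, from 6.72 ± 0.11 to 5.97 ± 0.04 (SD, n = 3), or 1.68-fold. In fibroblasts it fell by 1.41, from 7.67 ± 0.20 to 6.25 ± 0.01 (SD, n = 2), or 2.67-fold. Over the 3 tissues the mean change was -1.17 log2, with a two-sided exact permutation p of 0.0167, the smallest that the 120 arrangements can give when lungs and heart of a mouse are kept together. All 12 values of single probe sets and tissues were lower in KO, 11 of them with an unadjusted p under 0.05 and a change over 1.5-fold in limma. After adjustment over all kept probe sets, 0 of 12 were called, with the smallest adjusted p at 0.0674 in lungs (probe set 1419649_PM_s_at, -1.15, SE 0.18), 0.0825 in heart (1419648_PM_at, -1.10) and 0.0816 in fibroblasts (1419649_PM_s_at, -1.32). The exception in size was 1449550_PM_at in heart, at -0.17 with an adjusted p of 0.745, which turned to 0.08 after quantile normalization and to 0.05 without KO heart 1586. Leaving out 1 array gave up to 5 called Myo1c values, namely 5 without KO lungs 1602, 3 without WT lungs 1592, 2 without KO heart 1603 and 1 without WT fibroblasts 1571.

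**Figure D1:**
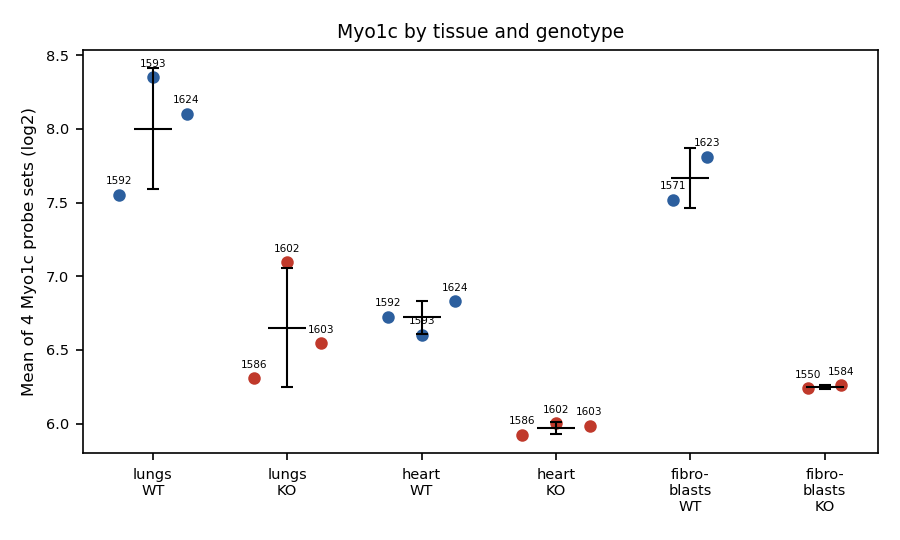
Mean log2 signal of the 4 Myo1c probe sets (vertical axis) in each tissue and genotype (horizontal axis), with 1 point per array, blue for WT and red for KO, and black bars for the mean ± SD. KO means lie below WT means in lungs (6.65 against 8.0), heart (5.97 against 6.72) and fibroblasts (6.25 against 7.67).

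In lungs, loss of NM1 went with a large rise of Xaf1 and Pisd-ps3 and a fall of Fam107a. Xaf1, an interferon-inducible gene for a factor that binds the apoptosis inhibitor XIAP, rose from 3.11 ± 0.30 log2 in WT to 9.52 ± 0.26 in KO lungs (SD, n = 3), a change of 6.41 (SE 0.82, adjusted p = 0.0173). The WT mean lay below the filter value of 3.79, so the size of the rise is uncertain. Pisd-ps3, a pseudogene of the phosphatidylserine decarboxylase gene Pisd, rose from 8.20 ± 0.98 to 11.32 ± 0.19 (SD, n = 3), or 8.72-fold (adjusted p = 0.0475). Sfi1, a gene for a centrosomal protein, rose from 7.87 ± 0.44 to 9.47 ± 0.26 (SD, n = 3, adjusted p = 0.0475). Fam107a, a stress-inducible gene for an actin-associated protein, fell from 7.97 ± 0.66 to 5.90 ± 0.25 (SD, n = 3), or 4.21-fold (adjusted p = 0.0173). Tent5b, a gene for a poly(A) polymerase, fell by 1.19 log2 (adjusted p = 0.0475). In all, 7 of 23218 probe sets were called, 4 higher and 3 lower in KO, among them 5 named genes, and 1617 had an unadjusted p under 0.05 against 1161 by chance alone. Of the unnamed probe sets, 1434914_PM_at fell by 2.12 log2 (adjusted p = 0.0173) and was chosen for naming after its values were seen.

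Other probe sets of the same lungs genes did not always follow. A second probe set of Xaf1, 1443698_PM_at, had the opposite sign in lungs (-1.19, adjusted p = 0.364), and of 4 other Sfi1 probe sets 2 shared its sign. Among genes that did not pass, Pisd had a change of 1.23 (adjusted p = 0.183), the hedgehog-binding gene Hhip -1.23 (0.108), the chitinase gene Chia1 -0.84 (0.127), the endothelin gene Edn1 -1.12 (0.415), Parp14 0.72 (0.300) and the transcription factor gene Klf5 0.91 (0.447). The calls leaned on single arrays, with 0 probe sets called without KO lungs 1586, 1 without WT 1593, 3 without KO 1603, 19 without WT 1592 and 62 without KO 1602. Xaf1 kept a change of 6.41 to 6.57 but lost its call without KO lungs 1603 (adjusted p = 0.0840), KO 1586 (0.0909), WT 1624 (0.0601) or WT 1593 (0.0914), and Fam107a lost it without KO 1586 (0.0909). The calls of Pisd-ps3, Sfi1 and Tent5b ended without KO 1603, KO 1586, WT 1592 or WT 1593, at adjusted p from 0.0616 to 0.319, and that of Tent5b also without WT 1624 (0.204). That of 1434914_PM_at ended without KO 1603 (0.0761), KO 1586 (0.0909), WT 1624 (0.0514) or WT 1593 (0.0914). In a fit of the lungs arrays alone 1 probe set was called, and without the 3 lungs samples that held adipocyte transcripts 47 were, 1 of them among the 7. The latter was chosen after seeing the data and leaves 1 KO against 2 WT lungs, with the lone KO sample assumed to vary like the other groups.

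Of the 42 gene lists, 8 were called by camera in lungs, 5 higher and 3 lower, and none with an estimated correlation. All 46 members of the oxidative phosphorylation list, genes of the respiratory chain, lay higher in KO lungs, with a median of 0.19 log2 (adjusted p = 7.36e-21 by camera, adjusted p = 0.963 with an estimated correlation). Examples are Ndufb8 with 0.55, Ndufv1 with 0.37 and Ndufa8 with 0.31, none of which passed on its own, and 0 members were called when adjusted over the list alone. The 10 measured adipocyte markers had a median of 1.58 (adjusted p = 6.09e-05 by camera, and adjusted p = 0.970 with an estimated correlation). All 8 kept by the filter were higher, led by Ucp1, the uncoupling protein of brown fat, with 3.51, and Cidea, a lipid droplet gene, with 2.67. Adipocyte transcripts were uneven between animals, with list means of 8.55 and 9.06 log2 in KO lungs 1603 and 1586 and 7.46 in WT 1592, against 3.98 in KO 1602 and 4.78 and 4.75 in WT 1624 and 1593. The same 3 lungs samples had the highest oxidative phosphorylation means, 10.1, 10.1 and 9.97, against 9.70, 9.69 and 9.61 in the others. They also had the highest means of atrial muscle transcripts, 8.05, 7.37 and 7.89 against 5.51 to 6.36. Without KO 1586 the adipocyte list lost its call (adjusted p = 0.0999).

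Of the other lists called in lungs, the interferon list had 17 of 22 members higher (median 0.19, adjusted p = 2.43e-04, and adjusted p = 0.970 with an estimated correlation), among them Oas2, a sensor of viral RNA, with 0.49, and Xaf1, the only member called when adjusted over the list alone. It lost its call without KO 1602 (adjusted p = 0.226) or WT 1592 (0.525), where the median was 0.01 and -0.06. List means were 6.68 in KO lungs 1602 and 5.61 in WT 1592 against 6.12 to 6.34 in the others. Xaf1, with its change of 6.41, weighs on these means and on the mean change of 0.39 over 26 measured members. The list was not tested without Xaf1. Among kept members, neutrophil markers such as S100a9 (1.79) and Mmp9 (0.61) were higher in 5 of 6 cases (9 measured, adjusted p = 0.0497 by camera). T and NK cell markers were higher in 8 of 8 (12 measured, 0.0378). With an estimated correlation the adjusted p was 0.970 for neutrophil and 0.963 for T and NK cell markers. The neutrophil call ended without KO 1603 (0.233), KO 1586 (0.260) or WT 1624 (0.415) and after quantile normalization (0.0842). The T and NK cell call ended without KO 1603 (0.109), KO 1586 (0.0839) or WT 1592 (0.639) and after quantile normalization (0.0842). For the 39 measured cell cycle genes the median in lungs was -0.22 (adjusted p = 3.08e-04 by camera, and adjusted p = 0.963 with an estimated correlation). Lower in KO lungs were 20 of the 22 kept by the filter, with Top2a, a topoisomerase of dividing cells, at -0.65 and Tyms, which makes thymidylate, at -0.44. So were 30 of 33 extracellular matrix genes (median -0.31, adjusted p = 0.0142), with Bgn at -0.49 and Mmp2 at -0.60, and 15 of 16 heat shock and unfolded protein genes (median -0.20, adjusted p = 0.0312), with Xbp1 at -0.24 and Herpud1 at -0.28. Both had an adjusted p of 0.970 with an estimated correlation. The matrix call ended without KO 1602 (0.0978), KO 1586 (0.0968) or WT 1624 (0.102). The heat shock call ended without KO 1586 (0.977) or WT 1593 (0.511) and after quantile normalization (0.0842).

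In heart, Xaf1 and Fam107a changed as in lungs, and most of the other called genes were lower in KO. Xaf1 rose from 3.40 ± 0.25 log2 in WT to 8.44 ± 0.18 in KO hearts (SD, n = 3), a change of 5.04 (SE 0.82, adjusted p = 0.0432), again from a WT mean below the filter value. The second Xaf1 probe set was again lower, at 5.15 to 5.54 in KO against 6.25 to 6.53 in WT hearts. Rbp7, a retinoid-binding protein gene, rose from 7.20 ± 0.42 to 8.86 ± 0.21 (SD, n = 3, adjusted p = 0.0240) and Mrpl28, of the mitochondrial ribosome, by 1.05 (adjusted p = 0.0473). Fam107a fell from 6.68 ± 0.24 to 4.56 ± 0.20 (SD, n = 3), or 4.34-fold (adjusted p = 0.0140), and Ndel1, a regulator of the dynein motor, from 6.60 ± 0.06 to 4.67 ± 0.63 (SD, n = 3, adjusted p = 0.0226). The unnamed probe set 1434914_PM_at had the smallest adjusted p, falling from 6.54 ± 0.19 to 3.18 ± 0.15 (SD, n = 3, adjusted p = 1.01e-04), to below the filter value. Also lower were Slc25a37, the mitochondrial iron importer mitoferrin 1 (-1.69), the RNA-binding protein gene Rbms3 (-1.43), Hnmt, which degrades histamine (-1.37), the Wnt pathway gene Dixdc1 (-1.36) and the transcription factor gene Glis2 (-1.32). Pde1c, a cyclic nucleotide phosphodiesterase (-1.19), Nin, the centrosomal ninein gene (-1.18), and Dsc2, a desmosomal cadherin gene (-1.17), completed the 10 lower genes with the largest changes, at adjusted p from 0.0169 to 0.0473, and 1 of 4 other Pde1c probe sets had the opposite sign. The KO mean of Pde1c also lay below the filter value.

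Altogether 28 of 22098 probe sets were called in heart, 4 higher and 24 lower in KO, 20 of them in annotated genes and 8 unnamed, and 3746 had an unadjusted p under 0.05 against 1105 by chance alone. The median of all kept probe sets lay at -0.16 in heart and at -0.02 after quantile normalization, which called 25 probe sets, 11 higher and 14 lower, 15 of them among the 28. Left out 1 at a time, the heart arrays gave 3 calls without WT 1593, 5 without WT 1592, 12 without KO 1602, 40 without WT 1624, 113 without KO 1586 and 1054 without KO 1603. The Xaf1 call ended without KO 1602 (adjusted p = 0.0896), WT 1592 (0.0852), WT 1624 (0.0551) or WT 1593 (0.169), and that of Fam107a without WT 1593 (0.0618). Ndel1 lost its call without WT 1592 (0.0796) or WT 1593 (0.0996), Rbp7 and Slc25a37 without KO 1602, WT 1592 or WT 1593, at adjusted p from 0.0608 to 0.169. The other named calls ended without 1 or more of KO 1602, WT 1592, WT 1624 and WT 1593, at adjusted p from 0.0551 to 0.204, or, for Pde1c, because it fell below the filter. The probe set 1434914_PM_at was called without each array. A fit of the heart arrays alone called 2 probe sets, both among the 28.

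Of the gene lists, 6 were called by camera in heart, 5 lower and 1 higher, and none with an estimated correlation. No member of these 6 lists was called when adjusted over all kept probe sets. Counts of members lower or higher are again over those kept by the filter. All 32 kept extracellular matrix genes were lower in KO hearts (median -0.72 over 36 measured, adjusted p = 2.19e-09 by camera, and adjusted p = 0.846 with an estimated correlation). Of the 32, 20 passed when adjusted over the list alone. They include Fn1, the fibronectin gene (-1.89), Fmod, the fibromodulin gene (-2.09), the collagen VI gene Col6a1 (-0.94) and the protease inhibitor gene Timp2 (-0.93). Fibroblast markers were lower in 10 of 10 cases (median -0.48, adjusted p = 0.0238), with Vim, the vimentin gene, at -0.73 and Tcf21, a fibroblast transcription factor gene, at -0.99 as the 2 called when adjusted over the list alone. Immediate early genes were lower in 16 of 16 cases (median -0.61, adjusted p = 5.54e-04), with Nr4a1 at -1.34, called when adjusted over the list alone, and Klf4 at -0.70. All 6 kept atrial genes were lower (median -1.96 over 7 measured, adjusted p = 0.0238 by camera), and 4 passed when adjusted over the list alone. Changes were -4.97 for Myl7 and -4.56 for Myl4, the atrial myosin light chain genes, and -3.28 for Dkk3. All 6 markers of mesothelium, the lining of the heart surface, were lower (median -1.28, adjusted p = 0.0172), with Lrrn4 at -2.42, which fell when adjusted over the list alone, and Upk3b at -1.82. With an estimated correlation, adjusted p = 0.846 for the fibroblast, immediate early and atrial lists and adjusted p = 0.891 for mesothelium. Oxidative phosphorylation genes were higher in 39 of 46 cases (median 0.07, adjusted p = 0.0116, and adjusted p = 0.927 with an estimated correlation), with Ndufs6 at 0.16 and 0 called when adjusted over the list alone.

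List means differed between single heart samples, within each genotype as well. Means of the atrial list were 5.06 and 5.55 log2 in KO hearts 1602 and 1586 and 8.85 in KO 1603, against 9.09, 8.18 and 9.42 in the WT hearts. Mesothelium means were 3.91 and 3.96 in KO 1602 and 1586, 6.38 in KO 1603, and 7.37, 5.50 and 5.68 in WT. Extracellular matrix means were 6.30 and 6.53 in KO 1602 and 1586, 7.17 in KO 1603, and 7.17, 7.30 and 7.75 in WT 1592, 1624 and 1593. With the mean of the atrial markers as a term, an alternative chosen after seeing the data, the matrix list was still called (adjusted p = 0.0151) but its median shrank from -0.72 to -0.24, and the mesothelium median turned to 0.19. The fibroblast list lost its call (0.214, and 0.236 without the KO hearts low in atrial transcripts). With this term 2 probe sets instead of 28 were called, while the median change of the 24 called lower went from -1.26 to -1.05, or 83.6% of its size (44.2 to 91.6% when 1 array was left out). The matrix call held without each array. The atrial call ended without KO 1586 (0.292), WT 1592 (0.0662) or WT 1593 (0.0753), the mesothelium call without KO 1586 (0.287) or WT 1592 (0.225), and the fibroblast call without KO 1586 (0.205) or WT 1593 (0.173). The immediate early call ended without WT 1593 (0.144), where the median was -0.30. This heart had a list mean of 7.37, against 6.56 and 6.20 in the other WT hearts and 5.90, 6.27 and 6.07 in KO. The oxidative phosphorylation call ended without KO 1602 (0.312) or WT 1593 (0.131) and after quantile normalization (0.240).

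**Figure D2:**
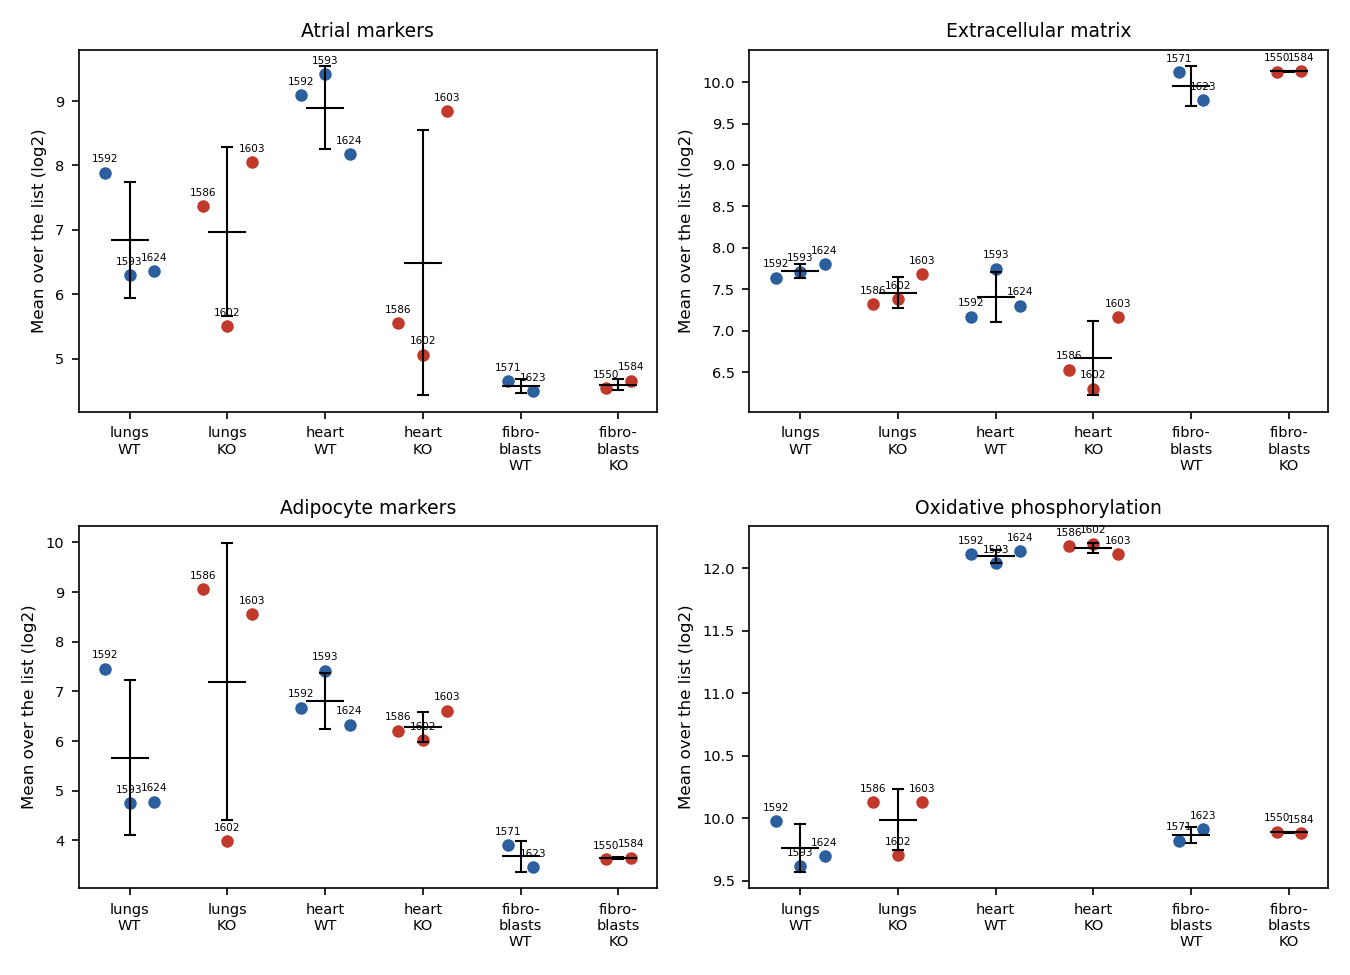
Mean log2 signal of the members of 4 gene lists (atrial markers, extracellular matrix, adipocyte markers and oxidative phosphorylation) (vertical axis, 1 panel per list) in each tissue and genotype (horizontal axis), with 1 point per array labelled by mouse number, blue for WT and red for KO, and black bars for the mean ± SD. Atrial means reach 5.06 and 5.55 in KO hearts 1602 and 1586, below the 8.18 to 9.42 of WT hearts, and adipocyte means reach 8.55 and 9.06 in KO lungs 1603 and 1586.

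In skin fibroblasts, KO cells had higher levels of Chodl, Lrrc15 and Moxd1 and a lower level of Il1rn. Chodl, the gene of the membrane lectin chondrolectin, rose from 3.37 ± 0.18 log2 in WT to 6.69 ± 0.34 in KO (SD, n = 2), a change of 3.32 (SE 0.30, adjusted p = 4.59e-04). Lrrc15, a membrane protein gene of activated fibroblasts, rose from 4.05 ± 0.41 to 6.86 ± 0.75 (SD, n = 2, adjusted p = 0.00147), and Moxd1, a monooxygenase gene, from 3.34 ± 0.63 to 5.61 ± 0.14 (SD, n = 2, adjusted p = 7.22e-04). Smaller rises were those of the vesicle GTPase gene Rab3c (1.46, adjusted p = 0.0450), the transporter genes Slc6a17 (1.41, 0.0450) and Slc1a6 (1.21, 0.0207) and the scaffold gene Dlg2 (1.07, 0.0199). Il1rn, which encodes the antagonist of the interleukin 1 receptor, fell from 5.23 ± 0.22 to 3.77 ± 0.06 (SD, n = 2, adjusted p = 0.0271). The WT means of Chodl, Moxd1 and Dlg2 and the KO mean of Il1rn lay below the filter value of 3.79, so the size of these changes is uncertain. Xaf1 was not called in fibroblasts, with a change of 2.70 (adjusted p = 0.9999), and WT 1571 had 8.63 log2 and WT 1623 had 3.54 against 8.67 and 8.91 in KO, a spread that also enters the SE of Xaf1 in lungs and heart. Among genes that did not pass, the R-spondin receptor gene Lgr5 had 3.25 (0.0923), the dystrophin gene Dmd 1.48 (0.0923), Spats2l 1.06 (0.0923), the histone gene H2aw -1.51 (0.124) and Ndel1 -1.50 (0.283). The change of Lgr5 ranged from 1.84 to 4.66 over the alternatives.

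In total, 12 of 21841 probe sets were called in fibroblasts, 10 higher and 2 lower, or 7 higher and 4 lower after quantile normalization, and 727 had an unadjusted p under 0.05 against 1092 by chance alone. Of the 12, 8 were named genes, and the unnamed probe set 1423477_PM_at rose by 2.84 (adjusted p = 4.39e-04). Its WT mean of 3.19 lay below the filter value, so the size of this rise is uncertain. The calls rest on the spread estimated over all 6 groups, since a fit of the 4 fibroblast samples alone called 0 probe sets, with Chodl at an adjusted p of 0.512. Chodl, Lrrc15 and Moxd1 stayed higher in KO without each fibroblast sample. Each such fit left a single sample in an arm. In these fits and in the main fit the spread came mainly from lungs and heart, where the group means of these genes lay below the filter value. The p-values of Chodl, Lrrc15 and Moxd1 may therefore not reflect the spread between fibroblast samples. Rab3c lost its call without KO 1584 (0.269), KO 1550 (0.195) or WT 1571 (0.103), Slc6a17 without KO 1550 (0.233) or WT 1623 (0.10), Slc1a6 without KO 1584 (0.113), KO 1550 (0.164) or WT 1623 (0.0596), Dlg2 without KO 1584 (0.165) and Il1rn without KO 1584 (0.189), KO 1550 (0.164) or WT 1571 (0.0695). Without WT 1571 the count was 92 and without WT 1623 it was 76. None of the 42 lists was called in fibroblasts by camera, with an estimated correlation (smallest adjusted p = 0.999) or by fry (smallest adjusted p = 0.991). The smallest adjusted p by camera was that of the p53 target list, 0.145, with 21 of 29 members lower. Adjusted over the list alone, Tnfrsf11b, the osteoprotegerin gene (1.40, list p 0.00118), Trib3, a stress-response gene (1.03, 0.0258), Tlcd2, a neighbour of Myo1c (1.17, 0.0363), and the endothelial gene Egfl7 (0.56) rose and Cd34 (-1.47, 0.0386) fell. None of these 5 genes was called over all kept probe sets, and the adjustment within a list does not cover the number of lists. Over the alternatives the change of Cd34 ranged from -2.46 to -0.48 and that of Tnfrsf11b from 0.88 to 1.91.

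**Figure D3:**
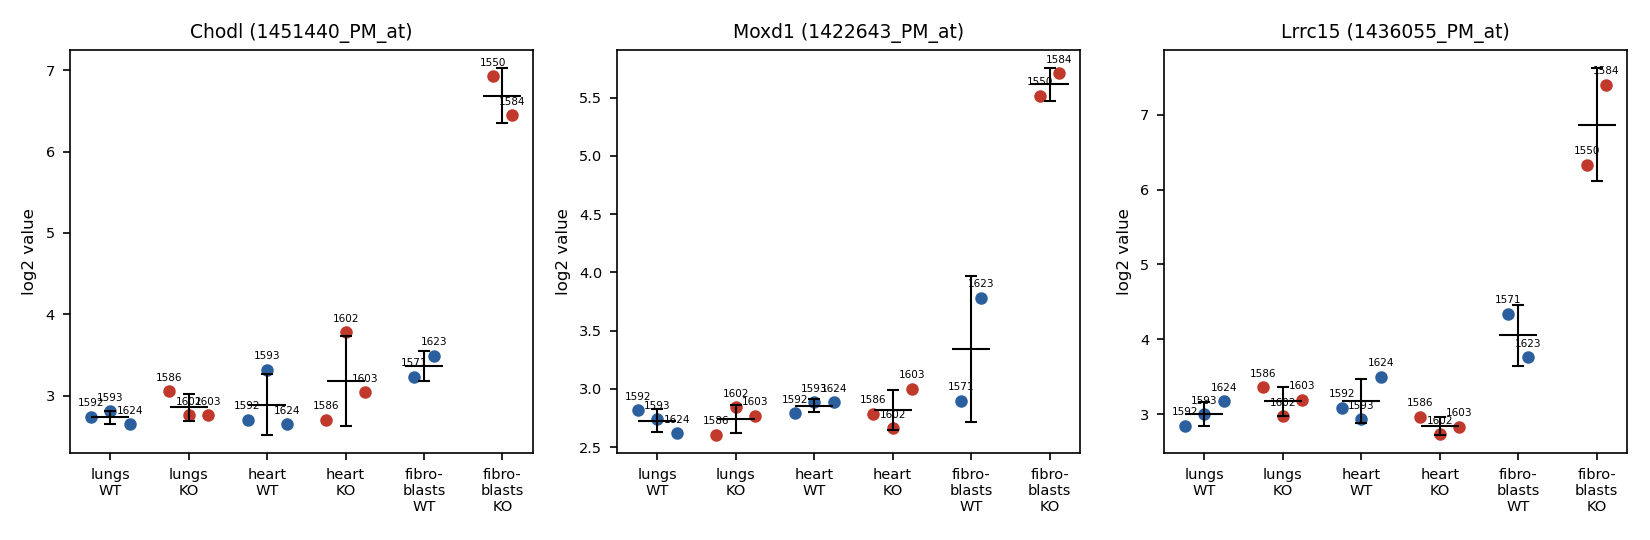
Log2 signal of Chodl, Moxd1 and Lrrc15 (vertical axis, 1 panel per gene) in each tissue and genotype (horizontal axis), with 1 point per array labelled by mouse number, blue for WT and red for KO, and black bars for the mean ± SD. In KO fibroblasts the means are 6.69, 5.61 and 6.86, against 3.37, 3.34 and 4.05 in WT fibroblasts.

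Some of the calls were shared between lungs and heart of the same mice. Xaf1, Fam107a and the unnamed 1434914_PM_at were called with the same sign in both tissues, 3 among the 20365 probe sets kept in both, from the same 6 mice. In the comparison of the mean of lungs and heart per mouse, Xaf1 rose by 5.73 (SE 0.12, adjusted p = 4.13e-06) and 1434914_PM_at fell by 2.74 (SE 0.15, adjusted p = 0.00220), the 2 calls among 23334 probe sets, of which 3234 had an unadjusted p under 0.05. Not called were, among others, Fam107a (-2.10), Ndel1 (-1.54), Rbp7 (1.19), Myo1c (-0.99) and Hnmt (-0.81), each with an adjusted p of 0.132, and Pisd-ps3 (2.63, 0.225). With the mouse as a random block over the 12 arrays, 12 probe sets were called, 5 higher and 7 lower, and without mouse 1592 or mouse 1624 the count per mouse was 4 or 5. The second Xaf1 probe set, 1443698_PM_at, was lower in KO in lungs (-1.19), heart (-1.03) and fibroblasts (-1.15). Across probe sets, which are not independent replicates, the genotype effects of lungs and heart correlated with r = 0.230, against 0.0436 to 0.223 for the 9 other splits of the 6 mice. The correlation was -0.0560 between lungs and fibroblasts and -0.0116 between heart and fibroblasts.

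**Figure D4:**
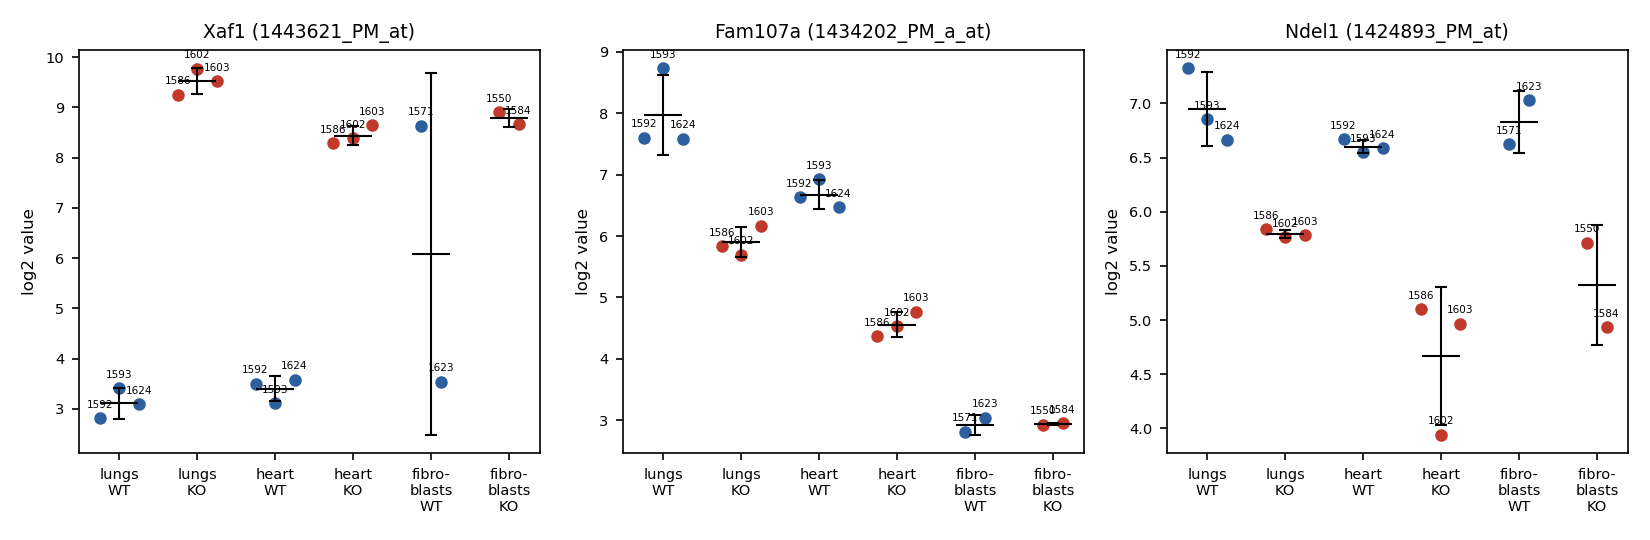
Log2 signal of Xaf1, Fam107a and Ndel1 (vertical axis, 1 panel per gene) in each tissue and genotype (horizontal axis), with 1 point per array labelled by mouse number, blue for WT and red for KO, and black bars for the mean ± SD. Xaf1 lies between 8.29 and 9.77 in KO lungs and hearts and between 2.81 and 3.58 in WT, and WT fibroblasts 1571 lie at 8.63.

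The genotype effect itself was compared between tissues. Against fibroblasts, the effect on Chodl was lower by 3.20 in lungs and by 3.03 in heart (-3.20 and -3.03, adjusted p = 0.0173 and 0.0121), that on Moxd1 was -2.26 and -2.31 (0.0179 and 0.0117) and that on Lrrc15 -2.64 and -3.14 (0.0492 and 0.0117). These genes had group means between 2.72 and 3.18 log2 in lungs and heart, below the filter value of 3.79. A fall there could not be seen, while Chodl changed by 0.12 and 0.29, Moxd1 by 0.01 and -0.04 and Lrrc15 by 0.17 and -0.33, so the differences come mainly from the rise in KO fibroblasts. Each of these comparisons called 5 probe sets, each with the lower effect outside fibroblasts (1 higher and 4 lower after quantile normalization for heart), of 25384 and 24631 tested, and 1109 and 1915 had an unadjusted p under 0.05. The difference between lungs and fibroblasts depended on single samples, with 0 calls without KO lungs 1603, WT lungs 1592 or WT lungs 1593, 1 without WT lungs 1624, 2 without KO lungs 1586, 3 without KO fibroblasts 1550, 8 without KO 1584, 24 without WT 1623 and 32 without WT 1571. It also shrank to 1 call after quantile normalization, where the adjusted p of Chodl, Moxd1 and Lrrc15 was 0.104. Between heart and fibroblasts the median of all kept probe sets was -0.18, and -0.03 after quantile normalization, where the Chodl call ended (0.0731). The counts were 46 without WT fibroblasts 1571, 33 without WT 1623, 11 without KO heart 1603 and 9 without KO fibroblasts 1584, with the Moxd1 call ended in the last case (0.0558) and the Chodl call without KO 1550 (0.0750). Between lungs and heart limma called 0 of 24947 probe sets, with 1802 at an unadjusted p under 0.05, and 0 with the mouse as a random or fixed block. The smallest p belonged to Pde1c (1.19), Zkscan6 (-0.96), Tent5b (-1.26), Pcnx3 (0.99) and Acly, the ATP citrate lyase gene (1.57), all at an adjusted p of 0.656, and 4 probe sets were called without KO lungs 1602 and 2 without WT heart 1624.

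WT lungs and WT heart of the same mice differed widely, as a reference for the size of the genotype effects. Of 24947 probe sets, 15017 were called, 8692 higher in lungs and 6325 higher in heart, and with the mouse as a fixed block, paired, 14625 were. The median over the kept probe sets was 0.18 toward lungs, and 0.04 after quantile normalization. Large changes toward lungs were those of the airway cytochrome gene Cyp2f2 (10.26 log2), the surfactant protein gene Sftpa1 (10.23), Ager (10.15), a marker of alveolar type I cells, Scgb3a2 (9.93), an airway secretory gene, and Sftpc (9.93). Toward heart there were those of Myl2 (-9.97), the natriuretic peptide gene Nppb (-7.86), phospholamban (Pln, -7.78), the myosin binding protein gene Mybpc3 (-7.53) and the skeletal actin gene Acta1 (-7.36). Their order is not meaningful. Several of these genes were near the background of the array in the other tissue, as with Sftpa1 at 2.90 in WT heart and Nppb at 3.08 in WT lungs, so that the size of their changes is uncertain. Myo1c was higher in WT lungs than in WT heart for all 4 probe sets, by 1.18 to 1.39 log2 at adjusted p from 3.3e-05 to 0.00968.

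The lists closest to the known roles of NM1 were not called in any tissue. Camera gave an adjusted p of 0.840 in lungs, 0.635 in heart and 0.692 in fibroblasts for RNA polymerase I and its factors, 0.101, 0.0715 and 0.216 for ribosome biogenesis, and 0.0793, 0.0715 and 0.878 for NM1 partners and chromatin remodelling. In the same order it gave 0.831, 0.776 and 0.878 for other myosins, 0.632, 0.891 and 0.216 for cytoskeletal and membrane functions of MYO1C, 0.252, 0.150 and 0.145 for p53 targets, 0.777, 0.357 and 0.955 for neighbours of Myo1c, and 0.429, 0.775 and 0.878 for mitochondrial biogenesis. Ribosome biogenesis genes were lower in 27 of 38 cases in lungs and 33 of 38 in heart and higher in 33 of 37 in fibroblasts. Neighbours called when adjusted over the list alone were Sgsm2 in lungs (0.49, list p 0.0292) and Glod4, a glyoxalase domain gene, in lungs (-0.49, 0.0292) and heart (-0.73, 0.00201), and Tlcd2 in fibroblasts (1.17, 0.0363).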

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

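The tests of flanking DNA, of Xaf1 across all samples and of the heart changes after quantile normalization, the use of the excess of lower calls in judging the heart tests, and the alternatives with atrial or adipocyte terms, were chosen after the results were seen.

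The genotype effect differed from that in fibroblasts for 5 probe sets in lungs and for 5 in heart, by limma's test of the difference itself. In lungs these were Chodl (-3.20), Moxd1 (-2.26), Lrrc15 (-2.64) and a pair of unnamed probe sets (-2.84 and -1.46). In heart they were Lrrc15 (-3.14), Chodl (-3.03), Moxd1 (-2.31) and a pair of unnamed probe sets (-2.88 and -3.22). The last, 1434914_PM_at, differed through its change in heart (-3.36). In fibroblasts its means were 3.89 in WT and 3.75 in KO, near the filter value, so a fall could hardly be seen there. Chodl, Moxd1 and Lrrc15 rose in KO fibroblasts and had group means between 2.72 and 3.18 log2 in lungs and heart, below the filter value of 3.79, so a fall there could not be seen. Control probe sets at the 3' and 5' ends of Gapdh and Actb, which were left out of the comparisons, read how complete the RNA was. The Gapdh difference between the ends was 1.5 log2 in KO lungs 1586, 0.34 in KO heart 1603 and 0.31 in KO heart 1586, each above the highest WT array of the tissue by more than the SD of the WT arrays, and likewise the Actb difference was 1.76 in KO lungs 1586.

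The first pattern is the rise of Xaf1 in KO lungs and hearts, a gene 143 genes away from Myo1c on the same chromosome of GRCm38.p6. Of 127 measured genes within 200 genes of Myo1c, 8 or 6.30% had an unadjusted p under 0.01 in the comparison per mouse, against a median of 3.08% and a 95th percentile of 6.41% in 107 windows on other chromosomes and 2.44% of 779 genes elsewhere on the chromosome. Xaf1, whose rise prompted this test, is 1 of the 8 and is also among those with the same sign in fibroblasts, so it adds to its own test. Of the 8, 62.5% had the same sign in fibroblasts, so DNA of another strain carried along with the KO allele, a candidate explanation, was neither shown nor excluded, and Ndel1, 360 genes away and outside this window, was lower in lungs (-1.15), heart (-1.93, called) and fibroblasts (-1.50). WT fibroblasts 1571, with a WT level of Myo1c (7.52), exceeded the lowest KO value of Xaf1, that of a heart (8.29), by 0.34 log2, but at 8.63 lay below the KO fibroblasts (8.67 and 8.91), so this 1 sample leaves an effect of NM1 loss on Xaf1 open. Of the other kept probe sets of these 8 genes, 25% moved the same way by at least 50% of the change, too few probe sets to tell a base difference under single probe sets from a changed transcript.

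The second pattern is the excess of lower calls in KO hearts. Without the dim array of KO heart 1602, the median change of the 24 probe sets called lower kept 92.4% of its size (80.5 to 100% when 1 more array was left out), and after quantile normalization it kept 90.8% (79.8 to 92.2%). These probe sets were picked for being lower, and the excess itself went from 4 higher and 24 lower to 4 and 8 without that array and to 11 and 14 after quantile normalization, where the median of all kept probe sets went from -0.16 to -0.02, so the dim array and a difference in brightness both stay open. With the atrial markers as a term it kept 83.6%, but between 44.2 and 91.6% when 1 array was left out, and 2 probe sets instead of 28 were called, while the median of the 24 went from -1.26 to -1.05, and why the calls ended was not tested. Less atrial tissue in some KO samples and an effect of genotype on matrix genes may both be at work and cannot be told apart here.

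The third pattern is the higher oxidative phosphorylation list in KO lungs. With the adipocyte markers as a term the median of the list kept 35.2% of its size (-4.02 to 57.1% when 1 array was left out), going from 0.19 to 0.07, and with the Gapdh difference as a term it kept 65.6% (34.8 to 135%). Fat tissue carried along with some lungs could account for much of the shift, RNA integrity could account for part of it, and neither can be told apart from genotype with 3 mice per group. Atrial muscle transcripts were highest in the same lungs samples as adipocyte transcripts and were not tested as a term.

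The 6 mice can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In lungs the real split called 7 probe sets and the highest other 839, so 2 of 10 called as many as the real one. The split with 839 parts KO 1603, KO 1586 and WT 1592 from the other mice and so follows the adipocyte transcripts, which points to a structure of the samples. In heart the real split called 28 and the highest other 6, so 1 of 10 called as many. Per mouse it called 2 and the highest other 4, so 2 of 10 called as many, and for lungs minus heart it called 0 and the highest other 112, so all 10 did. For WT lungs against WT heart, 10 splits of the 6 arrays gave 15017 for the real one and 0 for the highest other, with 1 of 10 as large.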

How the results depend on the processing

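Alternatives with atrial or adipocyte terms, or without samples that stood apart in these transcripts, were chosen after the results were seen. Over 186 results, each a named probe set or list in 1 comparison, and 3101 values under alternatives, 2652 kept sign and side of the threshold, 304 lost a call, 132 gained one and 13 changed sign. The WT lungs against WT heart count stayed within 1.5 times its value except with 1 probe set per gene (6618), where fewer were tested. The signal over background limits what can be seen of dim genes.

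Counts are given as lungs, heart and fibroblasts for KO against WT, then named differences, the comparison per mouse and called Myo1c values, and the cause was not tested unless stated. Without a filter, lungs had 4, heart 10 and lungs minus fibroblasts 3, with more probe sets to adjust over. The stricter filter, which drops dim probe sets, left heart 0, fibroblasts 1, lungs minus fibroblasts 0, heart minus fibroblasts 0, per mouse 1 and Myo1c 2. Quantile normalization gave 1 for lungs minus fibroblasts and 3 for Myo1c, and trend and robust options gave 4 per mouse and 2 for Myo1c. Array weights gave lungs 129, fibroblasts 40, lungs minus fibroblasts 35, heart minus fibroblasts 14, per mouse 16 and Myo1c 6. With 1 probe set per gene, lungs had 3, heart 11, fibroblasts 3, both differences from fibroblasts 1 and 1, and per mouse 1. A threshold of 0.1 gave 13, 198 and 19, heart minus fibroblasts 8 and Myo1c 5. Unadjusted p under 0.05 with 1.5-fold gave 518, 2014 and 426, lungs minus heart 1441, lungs minus fibroblasts 916, heart minus fibroblasts 1683, per mouse 567 and Myo1c 11. The random block over 12 arrays gave 12 per mouse, and fits per tissue, with fewer arrays for the spread, gave 1, 2 and 0. A fixed block for mouse was not run within a tissue, since each mouse has 1 genotype.

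Leaving out 1 array at a time gave 0 to 62 in lungs, 3 to 1054 in heart, 12 to 92 in fibroblasts, 0 to 4 for lungs minus heart, 0 to 32 for lungs minus fibroblasts, 5 to 46 for heart minus fibroblasts, 2 to 5 per mouse and 0 to 5 for Myo1c. An arm left with 1 sample was assumed to vary like the other groups. The correlation of effects ranged from 0.189 to 0.244 for lungs and heart, -0.156 to 0.0650 for lungs and fibroblasts and -0.0893 to 0.0777 for heart and fibroblasts. For lungs and heart it was 0.207 without a filter, 0.285 with the stricter one and 0.190 after quantile normalization, and for heart and fibroblasts -0.118 and 0.0519. Called lists ranged from 6 to 13 in lungs, 2 to 9 in heart and 0 to 4 in fibroblasts. With an estimated correlation they were 0 in lungs and 0 in heart, with fry 0 and 0, and with the mean of all probe sets of a gene 1 in fibroblasts.

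Without the KO hearts low in atrial transcripts, heart had 2 calls, Upk3b 0.34, and the atrial list a median of -0.13 with the test turned upward and mesothelium 0.23. With the atrial term heart had 2 calls, Upk3b 0.28, Myl4 0.022, mesothelium 0.19 and oxidative phosphorylation -1.73e-04. Without the lungs with adipocyte transcripts, lungs had 47 calls and 13 lists, Ucp1 -0.23, Cidea -0.34, T and NK cells -0.11 and adipocytes -0.36, with 1 KO against 2 WT lungs left, since the samples that held the signal were gone. The interferon median in lungs was -0.065 without WT 1592. Myo1c 1449550_PM_at in heart was 0.084 after quantile normalization and ranged from -0.41 without KO 1602 to 0.051 without KO 1586.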

Other observations

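The glucocorticoid test was chosen after the result was seen, and its comparison with the splits of the mice was added as a condition after that, and the other values here are from lists fixed earlier.

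In heart, lists that were not called still held single genes past the threshold when adjusted over the list alone. That adjustment does not cover the number of lists. None of the list members named in this paragraph was called when adjusted over all kept probe sets. Erythroid genes fell in 5 cases, among them Alas2, the first enzyme of heme synthesis in red cells (-2.20, list p 0.0210), Bpgm (-1.04, 0.0210) and Slc4a1, the anion exchanger of red cells (-1.07, 0.0210), with an adjusted p of 0.150 for the list. Of the clock genes, Per2 (-1.12, 0.0257) and Bhlhe40 (-0.67, 0.0257) fell and Nfil3 (0.47, 0.0257) rose, with 0.150 for the list. Bmp4 (-0.93, 0.0162), Mgp (-0.77, 0.0162) and Ctsk (-0.93, 0.0231) of the bone list fell (list 0.900), with list means of 4.54 in both KO 1602 and KO 1586, the hearts low in atrial transcripts, and 4.77 in KO 1603 against 4.71, 4.69 and 4.90 in WT. Also lower were the smooth muscle myosin Myh11 (-1.52, 0.0130), the contractile genes Myl9 (-1.81, 0.0138) and Tpm2 (-1.44, 0.0172), and Pdpn (-1.09, 0.0331). In lungs, Marco, a macrophage receptor gene, fell (-0.55, 0.0310).

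For the remaining lists, camera gave an adjusted p in lungs, heart and fibroblasts of 0.0528, 0.235 and 0.696 for glycolysis, 0.885, 0.601 and 0.878 for the sarcomere, 0.776, 0.900 and 0.878 for bone, 0.927, 0.150 and 0.878 for erythroid genes and 0.574, 0.150 and 0.878 for clock genes. Fetal and stress genes of the heart had 0.574, 0.774 and 0.878, sex-linked genes 0.840, 0.752 and 0.892, endothelial markers 0.242, 0.142 and 0.878, smooth muscle markers 0.0528, 0.233 and 0.878, and myofibroblast markers 0.0528, 0.150 and 0.878. Macrophage markers had 0.429, 0.369 and 0.878, B and plasma cells 0.0793, 0.619 and 0.878, alveolar type 1 cells 0.738, 0.752 and 0.912, alveolar type 2 cells 0.840, 0.150 and 0.878, and cardiomyocytes 0.840, 0.752 and 0.878. Ciliated cells had 0.711, 0.267 and 0.878, club cells 0.927, 0.150 and 0.878, keratinocytes 0.954, 0.357 and 0.878, melanocytes and Schwann cells 0.840, 0.775 and 0.878, myogenic cells 0.949, 0.241 and 0.987, skeletal muscle 0.738, 0.150 and 0.955, and thymus 0.574, 0.965 and 0.734. Of the lists called in lungs, heart and fibroblasts gave 0.235 and 0.692 for cell cycle, 0.954 and 0.438 for interferon, 0.635 and 0.692 for heat shock, 0.150 and 0.999 for neutrophils, 0.774 and 0.878 for T and NK cells and 0.985 and 0.878 for adipocytes. Of those called in heart, lungs and fibroblasts gave 0.885 and 0.692 for immediate early genes, 0.927 and 0.878 for atrial genes, 0.840 and 0.878 for fibroblast markers and 0.949 and 0.878 for mesothelium. In fibroblasts the matrix list had 0.675 and oxidative phosphorylation 0.955.

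A hypothesis of a lower glucocorticoid response in KO mice came from Fam107a and was tested on a list of 30 glucocorticoid-responsive genes written after 5 of them (Fam107a, Fkbp5, Tsc22d3, Ddit4 and Per1) had been seen, which were left out. Of 24 measured members, 23 were lower in KO per mouse, with a median of -0.35 log2 against -0.09 for random lists, and 0% of 10000 random lists lay lower. Of the 10 splits of the mice, 2 had a median as far from 0, the highest other being 0.37, so a lower response may exist, but another grouping of the mice gives a shift of that size too.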
